A study of Arabidopsis thaliana with 10 samples.

How the data were processed

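Leaf RNA of Arabidopsis thaliana was measured on Affymetrix-type arrays in 10 groups, formed by 2 genotypes and 5 times. The genotypes were the Col-0 wild type and the rpp4 mutant, and the times were 0, 0.5, 2, 4 and 6 days after inoculation with Hyaloperonospora arabidopsidis Emwa1, an oomycete that causes downy mildew. Per the labels, the plants were 2 weeks old, days were 12 h long, and inoculated plants received 500000 spores per mL. The plants of 0 days had no treatment, so no mock-inoculated column was used, and the clock time of harvest is not given in the sources used here. The protocol speaks of leaves and the tissue label of seedlings.

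Per the labels' protocols, total RNA was isolated with a Qiagen RNeasy kit and made into biotin-labelled target with a small-sample labelling assay. The deposited values are intensity on a linear scale, with 1 column per group. Each column's title names replicates 1 and 2 together, which per the labels were 2 independent biological experiments. Whether their values were averaged or their RNA was pooled is not given in the sources used here, nor are the software, the summary of probes into probe sets, the normalization and the detection calls. Column medians lay between 0.852 and 0.906, so the scale is relative to an unstated reference. With 1 column per group there is no replicate within a group, and the number of arrays limits the precision.

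All 22810 probe sets, here called probes, entered the tests, 64 control probes among them. The platform annotation used here listed 14016 of the probes, 13513 with 1 gene and 503 with several, and the other 8794 are unnamed here. Of the probes with 1 gene, 13436 matched a locus of the reference gene table (assembly TAIR10.1), which was used only for names and for the order of genes. Locus codes are given where no symbol was matched. Where a gene with several probes is named, the brightest probe stood for it, while tests and medians of lists used every probe of their genes. This concerned the endoplasmic reticulum list, with 14 probes of 13 genes, whose adjusted p with 1 probe per gene was 0.0444 for the genotype and 0.000991 at 4 days. The 2 probes of DER1 differed in size at 4 days, with log2 changes of 0.04 and 0.42.

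Values were transformed as log2(value + 1), the transformation set for linear values before the data were examined. Since most values lay near 1, this scale understates the changes of dim genes, and ratios of geometric mean intensity are given beside it for the leading genes. Models were fitted with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with an intensity trend, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. The additive model held time and genotype, with 4 residual degrees of freedom, and gave the difference of wild type minus rpp4 and each time minus 0 days. Its error is the variation of the genotype difference across times, so a gene that differed at 1 time is not called. The trend model added the product of genotype and the rank of time, with 3 residual degrees of freedom. No test compared the genotypes at a single time, where only differences between 2 columns are given.

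Lists of genes were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Before the data were examined, 21 lists with 313 entries were fixed. Of these entries, 15 were dropped because symbol and locus did not match, and only 31 were measured by a probe with 1 listed gene, so that 5 lists kept the minimum of 3 members. A further 18 lists were made after the annotation was seen and before any gene was tested, from genes named on the array. Adjustment ran over the 5 fixed lists and over the 18 added lists separately, a split made after joint values had been seen so as to follow the plan. For differences between 2 columns, a list's median was placed among 10000 random lists of equal size matched on mean expression in 20 bins. RPP4 itself and PR1, PR2, PR5, ICS1, EDS1, PAD4, ALD1, FMO1, CCA1, LHY and TOC1 were on the list of genes to report first, and they are not analysed here because the annotation used gave none of them a probe of its own. The mutant's target therefore offered no check of the labels.

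Genes were named by a rule fixed before the data were examined. It took GI, up to 10 called genes per direction for the genotype and for the trend (of 1 sign at all times for the genotype), 5 per direction for each time, 5 per direction among brighter probes for each single-time difference, and up to 4 members of a list. Genes named outside it were chosen after their values were seen, and this is said where it applies.

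Alternatives set beforehand were quantile normalization, centring on column medians, removal of the dimmest 40% of probes, eBayes without trend, a pseudocount of 32, no block, a minimum log2 difference of 1, other codings of time, and leaving out each time. Chosen after seeing the data were log2 without a pseudocount and a fit without the columns of the wild type at 2 days and rpp4 at 6 days, whose range of intensities was narrowest. That fit rests on rpp4 alone at 2 days and on the wild type alone at 6 days, with fewer residual degrees of freedom. The order of genes around RPP4 was at first counted over protein-coding genes, which left out a called pseudogene, and was then counted over all gene records. Both counts are given.

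The fitting code was tested on simulated data for 22810 probes with 200 changed ones. Values were each probe's mean plus independent normal noise of its fitted spread, and the changed probes were brighter than the median. Effects shared by many probes of a column, such as a narrow range, were not simulated. The shares below therefore check the code and do not give the recovery or false calls of these data. For the genotype, 84% of log2 changes of 0.5 and 100% of changes of 1 were recovered. For times against 0 days the shares were 63% to 71% and 90% to 95%, and for the trend 22% and 62%. False calls made up 7.54% of calls for the genotype, 4.97% to 10.6% for the times and 18.4% for the trend. These shares were above the nominal level in all but the comparison at 0.5 days. Each came from 1 run and has no error, so it does not give the rate over repeated runs. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the list medians and figures.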

Results

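The data were 10 columns of array intensities from leaves, 1 for each of 2 genotypes at 5 times. The wild type Col-0 carries RPP4, a resistance gene for isolate Emwa1 of the downy mildew oomycete Hyaloperonospora arabidopsidis, and the rpp4 mutant lacks its function. Each column stood for 2 experiments together, so no value below has an error from replicates of its own group, and errors are standard errors of the fitted log2 values. The ratio of the 95th to the 5th percentile of intensity was 15.7, 15.7, 8.73, 13.0 and 14.2 in the wild type and 12.5, 13.7, 13.6, 12.1 and 10.2 in rpp4, in order of time. The column of the wild type at 2 days was thus the narrowest and that of rpp4 at 6 days the next, and they are called the narrow columns here. A fit without them rests on rpp4 alone at 2 days and on the wild type alone at 6 days. Its changes from 0 days at these times are thus not over both genotypes. A call lost in that fit can stem from fewer columns and need not stem from the narrow range. RPP4 itself was not analysed here.

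The comparison of the genotypes over all times asked which genes differed between resistant and susceptible plants. QQS, an orphan gene linked to starch metabolism, was higher in the wild type by 0.74 ± 0.08 on the log2 scale (adjusted p = 0.00425, limma), with a ratio of 2.41. COR15A, which encodes a cold-induced chloroplast protein, was higher by 0.59 ± 0.09, with a ratio of 2.00. Among the genes called lower in the wild type, AT4G12490 and AT4G12500, neighbouring genes of a lipid transfer protein family, differed by -0.92 ± 0.14 and -0.64 ± 0.08, and the peroxidase gene AT5G64120 by -0.90 ± 0.14. The ubiquitin ligase gene PUB23, whose product dampens pattern-triggered immunity, differed by -0.30 ± 0.05. AT5G64120 stood at 0.640 in the wild type and 1.68 in rpp4 at 0 days and at 4.00 and 10.9 at 6 days, and rpp4 was higher at every time.

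Over all probes, limma called 21 between the genotypes, 6 higher and 15 lower in the wild type, each with 1 sign at all 5 times. With each column centred on its median the split was 4 higher and 19 lower. At unadjusted p under 0.05 there were 1510 probes, where 1140 would be expected with no difference. The remaining called genes of the fixed rule were the pseudogene AT4G16870 at 0.36 and AT3G42820 at 0.22, and, lower in the wild type, AT1G52200 at -0.76, AT1G19020 at -0.53, AT2G43620, of a chitinase family, at -0.40, AT2G17740 at -0.36, the oxidase gene AT1G26380 at -0.34 and AT3G46280 at -0.28. The genotype count fell to 0 without 2 days (6218 at unadjusted p under 0.05) and after quantile normalization (2299), and came to 34 without 0.5 days and 32 without 4 days. Without 2 days QQS differed by 0.69 and AT4G12490 by -0.98, both with an adjusted p of 0.0648. Without 0 days AT3G42820, AT4G12490, AT5G64120, AT1G52200, AT1G19020, AT2G43620 and AT3G46280 were not called (adjusted p from 0.0575 to 0.109), nor was AT4G12490 without 0.5 days (0.0896) or AT3G42820 without 6 days (0.0522).

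Of the 5 fixed lists, 4 ranked apart from other probes between the genotypes. The cold and abscisic acid list ranked higher in the wild type (camera adjusted p = 6.81e-05; adjusted p = 0.107 with an estimated correlation). Of its 4 members COR15A was called and 2 were higher when adjusted over the list alone; COR15B differed by 0.42 ± 0.07 (adjusted p = 0.0555, and 0.0102 without 0.5 days and 0.0139 without 4 days) and COR47 by -0.01 ± 0.14. The salicylic acid and EDS1 list, here SAG101, WRKY53 and GRX480, ranked lower in the wild type (adjusted p = 0.000102; adjusted p = 0.171 with an estimated correlation). None of the 3 was called over all probes and 3 were lower when adjusted over the list alone, with WRKY53 at -0.30 ± 0.09. The jasmonate and ethylene list ranked lower (adjusted p = 0.0286; adjusted p = 0.327 with an estimated correlation) and the photosynthesis list higher (adjusted p = 0.0286; adjusted p = 0.346 with an estimated correlation), with 0 members of either called over all probes or adjusted over the list alone. After quantile normalization the jasmonate and ethylene list did not rank apart (0.273). PDF1.2b, a defensin gene whose probe can hybridise with related genes, differed by -0.52 ± 0.22. The guard cell and stomatal list did not rank apart (adjusted p = 0.345), with 0 of 3 members called either way.

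Among the 18 added lists, 8 ranked apart between the genotypes and none did with an estimated correlation. The list of 23 immunity genes ranked lower in the wild type (adjusted p = 2.99e-15; adjusted p = 0.485 with an estimated correlation), with a median of -0.12, 22 members below 0 and 1 called member, PUB23. Both photosynthesis lists ranked higher, the 43 chloroplast-encoded genes with a median of 0.17 (adjusted p = 2.51e-07; adjusted p = 0.513 with an estimated correlation) and the 28 nuclear genes with a median of 0.20 (adjusted p = 4.7e-07; adjusted p = 0.513 with an estimated correlation). No member of either was called. At single times the median of the chloroplast-encoded genes was 0.43 in untreated plants (percentile 100 of matched random lists), 0.12 at 0.5 days (percentile 25.7), -0.07 at 2 days (percentile 100), 0.11 at 4 days (percentile 81.3) and 0.20 at 6 days (percentile 0.49). After quantile normalization it was 0.32, -0.07, 0.14, 0.06 and 0.02, with the sign changed at 0.5 and 2 days. The wild type column of 0 days also had the highest values of the GAPDH probe sets, 10.2 at the 5' end and 16.7 at the 3' end. The cytokinesis and replication list ranked higher with a median of 0.06 (adjusted p = 0.000247; adjusted p = 0.485 with an estimated correlation). Lists that ranked lower were those of autophagy (adjusted p = 0.0173), branched-chain amino acid breakdown (0.0198), endoplasmic reticulum quality control (0.0362) and UGT glycosyltransferases (0.0444), whose adjusted p with an estimated correlation lay between 0.485 and 0.561. The other 10 did not rank apart. These were the jasmonate and defensin genes (0.0613), CYP71B (0.0613), glutathione S-transferases (0.12, and 0.0305 after quantile normalization), sugar transporters (0.144), pollen (0.92), root hairs (0.927), BGLU (0.994), expansins (0.994), TBL (0.994) and clock-regulated genes (0.994). The jasmonate and defensin genes ranked lower with a mean of -0.09 but had a median of 0.02, and the lists of expansins, TBL and clock-regulated genes had medians just above 0 while their tests pointed lower.

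The comparisons of each time with 0 days asked what changed over both genotypes after inoculation. All 4 share the columns of 0 days, whose plants were untreated, so inoculation, age and time of day were not separated. In the wild type column of 0 days the 5' probe set of GAPDH stood at 10.2, against at most 6.91 in the other 9 columns. The 3' and middle probe sets were also highest there, at 16.7 and 22.7, against at most 14.6 and 18.5. The excess was thus not confined to the 5' end, but in proportion it was largest there, and its cause was not tested. Of the 18 added lists, 4 ranked apart at 0.5 days, 4 at 2 days, 7 at 4 days and 8 at 6 days, and none with an estimated correlation.

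At 0.5 days LCR69, a defensin-like gene, rose by 1.91 ± 0.24 on the log2 scale (adjusted p = 0.000447, limma), a ratio of 4.33. COR27, regulated by cold and the clock, rose by 1.58 ± 0.09, a ratio of 7.37, and FDH, AT1G75800 and AT4G34950 by 1.65, 1.64 and 1.53. AT1G73600 fell by 1.81 ± 0.35, AT1G55960 by 1.78, AT1G65490 by 1.65, AT5G35970 by 1.63, and BCAT4, an enzyme gene of glucosinolate synthesis, by 1.58 ± 0.28. GI, a clock gene, fell by 0.32 ± 0.08. A total of 987 probes rose and 459 fell, or 959 and 690 after quantile normalization and 1322 and 725 without 2 days. With eBayes without trend 866 rose and 132 fell, and with a pseudocount of 32 these were 980 and 287. The 5S ribosomal RNA control probe stood at 3.78 in the wild type and 2.71 in rpp4 at this time, against 0.507 to 0.655 in the other 8 columns. Without the narrow columns AT5G35970 was not called (adjusted p = 0.062).

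The cold and abscisic acid list ranked higher at 0.5 days, with 3 of 4 members called, COR15A at 0.87 ± 0.15, COR47 at 0.82 ± 0.22 and COR15B at 0.45 ± 0.12, LTI30 at 0.07 not called, and 3 adjusted over the list alone (adjusted p = 0.00121; adjusted p = 0.264 with an estimated correlation). The photosynthesis list ranked lower (adjusted p = 0.00364; adjusted p = 0.3 with an estimated correlation), with LHCB4.2 falling by 1.38 ± 0.30 as its 1 call and 3 adjusted over the list alone. COR47 was not called without 4 days (adjusted p = 0.0728), COR15B after quantile normalization (0.0585) and LHCB4.2 without the narrow columns (0.0665). Of the 8 genes of branched-chain amino acid breakdown, 4 rose, among them MCCA by 0.89 ± 0.17 and IVD by 0.83 ± 0.10 (adjusted p = 1.02e-05; adjusted p = 0.694 with an estimated correlation). The autophagy list ranked higher (adjusted p = 0.00123; adjusted p = 0.694 with an estimated correlation), with ATG8D rising by 0.55 ± 0.07, and so did the clock-regulated list (adjusted p = 0.0309; adjusted p = 0.729 with an estimated correlation), with CCL rising by 1.38 ± 0.23, though not after quantile normalization (0.0686). The nuclear photosynthesis list ranked lower (adjusted p = 0.0001; adjusted p = 0.802 with an estimated correlation), with 3 of 28 members called. Of the fixed lists, the salicylic acid and EDS1 (adjusted p = 0.79), jasmonate and ethylene (0.128) and guard cell (0.605) lists did not rank apart, with 0, 2 and 0 members adjusted over the list alone.

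At 2 days 66 probes were called, 29 higher and 37 lower. AT5G03350, of a lectin family, rose by 2.03 ± 0.26 (adjusted p = 0.00868, limma), a ratio of 4.84, AT3G22240 by 1.59, AT4G12490 by 1.54 ± 0.22, AT3G18250 by 0.98 and AT2G37130 by 0.93. AT4G21870 fell by 1.06, LHCB4.3, a light-harvesting gene, by 1.03 ± 0.19, AT5G12110 by 0.73, AT1G64500 by 0.72 and AT3G48460 by 0.63. The count for 2 days against 0 days was 0 without the narrow columns (965 at unadjusted p under 0.05), 12 after quantile normalization, 208 without 0.5 days, 302 without 4 days and 171 without 6 days. After quantile normalization, of the 10 genes named here only AT5G03350 was still called.

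The cold and abscisic acid list ranked higher at 2 days (adjusted p = 0.000752; adjusted p = 0.264 with an estimated correlation), with 0 of 4 members called and 3 adjusted over the list alone, COR47 at 0.77 ± 0.22. The jasmonate and ethylene (0.0708), photosynthesis (0.128), salicylic acid (0.227) and guard cell (0.313) lists did not rank apart, with 0 members adjusted over the list alone. Immunity genes ranked higher with a median of 0.09 (adjusted p = 0.000243; adjusted p = 0.722 with an estimated correlation), and 20 of the 23 lay above 0 without any being called. The CYP71B list ranked higher (adjusted p = 0.00164), and the chloroplast-encoded (adjusted p = 1.52e-11) and nuclear photosynthesis lists (adjusted p = 0.000555) lower. Their adjusted p with an estimated correlation was 0.698, 0.694 and 0.802. Only LHCB4.3 was called among these members. After quantile normalization the nuclear list no longer ranked apart (adjusted p = 0.418), and the autophagy list ranked higher (0.0268, against 0.362 as deposited).

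At 4 days AT4G12490 rose by 2.68 ± 0.22 (adjusted p = 2.11e-05, limma), a ratio of 12.6, AT5G03350 by 2.45, AT3G18250 by 2.01 and AT3G22240 by 1.87. AT1G35710, a leucine-rich repeat receptor kinase gene, rose by 1.82 ± 0.18. AT4G21870 fell by 1.32 ± 0.20, AT3G56290 by 1.01, the nitrate transporter gene AT3G21670 by 1.00, PMEAMT by 0.95 and AT1G06830 by 0.94. Among the immunity genes 8 of 23 rose, led by the chitinase gene CHI at 1.56 ± 0.20, SGT1A, a co-chaperone gene of immune receptors, at 0.98 ± 0.16, and the transcription factor gene WRKY53 at 0.68 ± 0.14. A total of 626 probes rose and 231 fell, or 676 and 418 without 0.5 days and 710 and 390 without 2 days. With eBayes without trend 375 rose and 33 fell, and with a pseudocount of 32 these were 273 and 63. After quantile normalization AT3G56290 (adjusted p = 0.0601) and WRKY53 (0.094) were not called.

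The salicylic acid and EDS1 list ranked higher at 4 days (adjusted p = 0.000752; adjusted p = 0.264 with an estimated correlation), with WRKY53 and GRX480 called and 3 adjusted over the list alone. The jasmonate and ethylene list also ranked higher (adjusted p = 0.0222; adjusted p = 0.3 with an estimated correlation), with 1 call, PDF1.2 at 0.95 ± 0.23, and 2 adjusted over the list alone, but not after quantile normalization (0.0988). PDF1.2 was not called without 2 days (adjusted p = 0.0866), after quantile normalization (0.122) or without the narrow columns (0.102). The cold list ranked higher (adjusted p = 0.00243; adjusted p = 0.264 with an estimated correlation), with COR15B called and 3 adjusted over the list alone. The photosynthesis (0.162) and guard cell (0.111) lists did not rank apart, with 0 adjusted over the list alone. Immunity (adjusted p = 1.22e-10), CYP71B (0.000207), endoplasmic reticulum quality control (0.000975) and autophagy genes (0.0136) ranked higher, each with an adjusted p of 0.694 with an estimated correlation. Among them CYP71B23 rose by 1.09 ± 0.12, ATERDJ3B, a chaperone gene, by 0.94 ± 0.20 and APG8A by 0.65 ± 0.12. Chloroplast-encoded (7.3e-09), nuclear photosynthesis (0.00817) and sugar transporter genes (0.0151) ranked lower, with SWEET2 falling by 0.83 ± 0.15. Their adjusted p with an estimated correlation was 0.715, 0.802 and 0.694. After quantile normalization the nuclear list did not rank apart (0.172), and GRX480 (adjusted p = 0.0827), COR15B (0.0575) and ATERDJ3B (0.0607) were not called.

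At 6 days AT4G12490 rose by 3.37 ± 0.22 (adjusted p = 4.13e-06, limma), a ratio of 21.2, AT3G18250 by 2.44, AT5G03350 by 2.32, AT2G18690 by 2.05 and AT1G35710 by 1.97. AT1G55960 fell by 1.60, AT3G56290 by 1.51, EXO, a growth gene induced by brassinosteroid, by 1.36 ± 0.24, AT3G21670 by 1.31 and AT3G56360 by 1.28. GI rose by 0.80 ± 0.08. Of the 23 immunity genes 12 rose, among them CHI by 1.71 ± 0.20, SGT1A by 1.05 ± 0.16, OSM34 by 0.99 ± 0.13 and CML41 by 0.79 ± 0.13. A total of 1278 probes rose and 1092 fell, or 1649 and 1866 without 2 days, and the count for 6 days against 0 days was 667 without the narrow columns, 495 higher and 172 lower. In that fit AT1G55960 (adjusted p = 0.112), AT3G56360 (0.174) and CML41 (0.103) were not called.

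The salicylic acid and EDS1 list ranked higher at 6 days (adjusted p = 0.00364; adjusted p = 0.3 with an estimated correlation), with WRKY53 and GRX480 called and 3 adjusted over the list alone. The cold list ranked higher (adjusted p = 0.0122; adjusted p = 0.264 with an estimated correlation), with COR47 and COR15B called and 2 adjusted over the list alone. The guard cell list ranked lower (adjusted p = 0.0452; adjusted p = 0.264 with an estimated correlation), with FMA falling by 0.25 ± 0.07 and 3 adjusted over the list alone, but not after quantile normalization (0.0752). The jasmonate and ethylene (0.288) and photosynthesis (0.071) lists did not rank apart, with 0 and 2 adjusted over the list alone. Immunity (adjusted p = 1.06e-10), autophagy (0.000874), CYP71B (0.00117) and endoplasmic reticulum genes (0.00164) ranked higher, each with an adjusted p of 0.694 with an estimated correlation. Chloroplast-encoded (4.34e-08), nuclear photosynthesis (0.000108), cytokinesis (0.0151) and sugar transporter genes (0.049) ranked lower. Their adjusted p with an estimated correlation was 0.715, 0.802, 0.722 and 0.715. Among the chloroplast-encoded genes 9 of 43 fell, psbB by 1.12 ± 0.28 and ndhG by 1.02 ± 0.28, and PORB, a chlorophyll synthesis gene, rose by 0.93 ± 0.25 against the direction of its list. By genotype, the median change of the chloroplast-encoded genes from 0 to 6 days was -0.52 in the wild type (percentile 0 of matched random lists). In rpp4 it was -0.29 (percentile 68.2). After quantile normalization these were -0.39 (percentile 0) and -0.05 (percentile 78.1). The difference between the genotypes was not tested. The rpp4 column of 6 days was a narrow one, and the wild type column of 0 days had the highest GAPDH probe sets. Without the narrow columns WRKY53 (adjusted p = 0.0883), GRX480 (0.232), FMA (0.178), psbB (0.174) and ndhG (0.124) were not called, nor were FMA (0.0519) and ndhG (0.0534) without 2 days or GRX480 (0.0793), FMA (0.0531) and ndhG (0.0557) after quantile normalization.

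The fixed lists with fewer than 3 measured genes were read gene by gene. GAMMA-VPE, a vacuolar protease gene on the cell death list, rose at 6 days by 1.25 ± 0.28, while ALPHA-VPE was not called at any time. BZIP60, a transcription factor gene of the unfolded protein response, rose by 0.75 ± 0.17 at 6 days. DFR, of flavonoid synthesis, fell by 0.66 ± 0.18 at 6 days. None of these 3 was called without the narrow columns (adjusted p = 0.161, 0.0661 and 0.198), nor was DFR without 2 days (0.0746) or after quantile normalization (0.07). WRKY22 and EFR of the pattern-triggered immunity list, UGT74B1 of the glucosinolate list, EXPA7 and PYK10 of the root list and the reference genes GAPC2 and PEX4 were not called in any comparison. No member of the lists of NLR receptors, camalexin, morning clock genes, starvation, heat shock, cell division, epidermis and vasculature was analysed here.

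**Figure D1:**
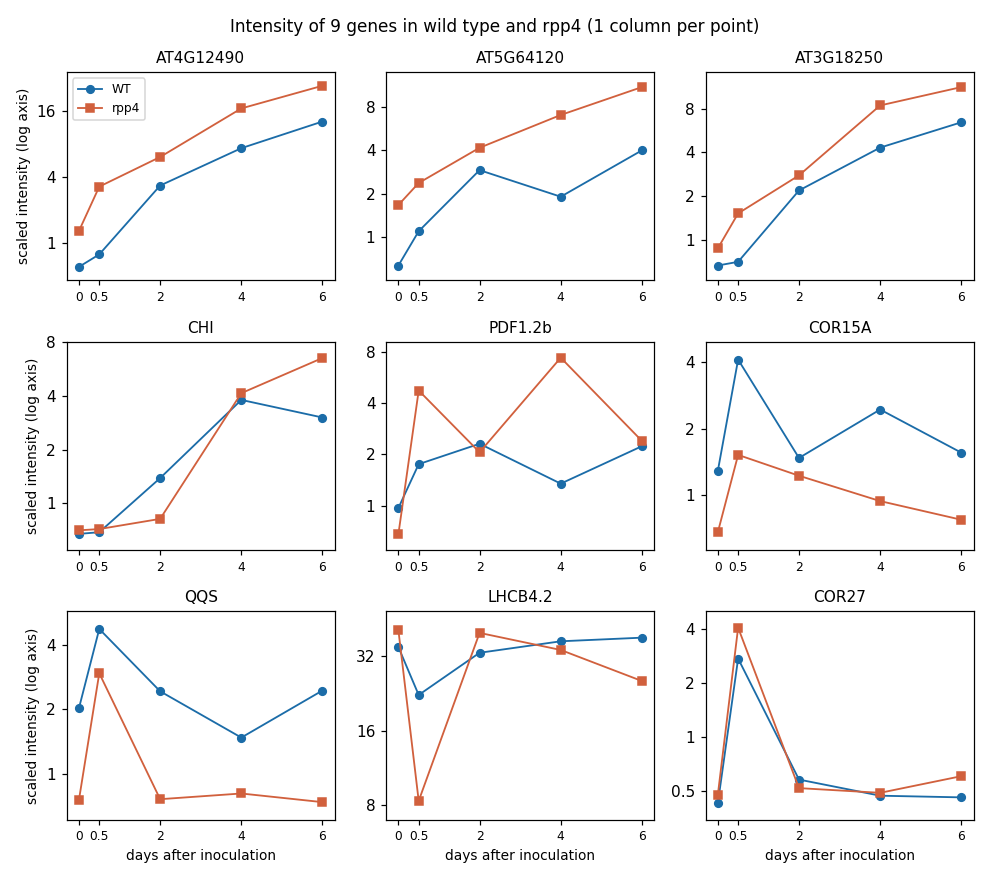
Scaled intensity (log axis) of 9 genes against days after inoculation, with 1 column per point, the wild type in blue circles and rpp4 in orange squares. AT4G12490 reached 12.9 in the wild type and 27.4 in rpp4 at 6 days, and QQS was higher in the wild type at all 5 times.

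The trend along the time course asked whether the genotype difference moved in 1 direction with time. AT1G05340 and the chitinase-family gene AT3G47540 moved towards rpp4 by -0.30 ± 0.05 and -0.29 ± 0.05 per step of time (adjusted p = 0.0101 and 0.00744, limma). AT1G05340 stood at 0.518 in the wild type and 0.764 in rpp4 at 0 days and at 1.16 and 4.43 at 6 days. UGT87A2 moved by -0.31 ± 0.05, AT4G03450 by -0.18 ± 0.03, AT1G67360 by -0.21 and AT4G22470 by -0.18, and CML41 of the immunity list by -0.18. AT1G47400, AT5G62210, AT5G55570 and LHCB4.3 moved by -0.37, -0.25, -0.21 and -0.24. AT1G47400 stood at 4.60 in the wild type at 0 days and between 0.548 and 0.694 in the other 9 columns, and its adjusted p was 0.999 without 0 days. AT1G56300 moved towards the wild type by 0.14 ± 0.03.

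Of the genes named for the trend, AT1G05340, AT3G47540 and AT4G03450 were called with any 1 time left out. Without 0 days the adjusted p was 0.0635 for UGT87A2, 0.929 for LHCB4.3, 0.506 for AT1G67360, and 0.999 for AT5G62210 and AT5G55570. Without 2 days it was 0.0598 for AT1G56300, 0.168 for AT1G47400, 0.155 for AT5G62210, 0.0718 for LHCB4.3 and 0.116 for AT5G55570. Without 6 days it was 1 for AT1G56300, 0.253 for AT1G67360, 0.384 for AT4G22470 and 0.152 for CML41.

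For the genotype by time trend, 73 probes were called, 4 towards the wild type and 69 towards rpp4, or 3 and 12 with columns centred on their medians. At unadjusted p under 0.05 there were 1449. Among the 4 was a control probe, at 0.16 per step (adjusted p = 0.00632, limma). It stood at 0.504 at 0 days and 1.43 at 6 days in the wild type, and at 0.556 and 0.580 in rpp4. Leaving out 1 time gave 153 without 0 days, 201 without 0.5 days, 139 without 2 days, 154 without 4 days and 127 without 6 days. No probe was called by limma after quantile normalization (2224 at unadjusted p under 0.05), and 15 were without the narrow columns.

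At single times the genotypes were compared without a test. At 0 days AT1G73600 was at 15.1 in the wild type and 3.45 in rpp4, and the chloroplast gene ndhG at 7.39 and 1.78, while CCS, encoding a copper chaperone, was at 1.11 and 4.78 and AT2G05540 at 6.72 and 26.7. At 0.5 days AT1G13650 was at 3.19 in the wild type and 0.469 in rpp4 and LHCB4.2 at 22.3 and 8.35, while AT3G23550 was at 1.79 and 6.68. At 2 days psaA was at 8.04 in the wild type and 20.9 in rpp4. At 4 days PDF1.2b was at 1.35 in the wild type and 7.38 in rpp4, PDF1.2 at 0.855 and 3.58, and AT3G16530 at 3.76 and 13.6, while COR15A was at 2.44 and 0.939. At 6 days BCAT4 was at 8.53 and 3.40, AT3G50685 at 14.7 and 6.15 and CHI at 3.03 and 6.54.

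The number of probes at least 1 apart on the log2 scale was 70, 43, 5, 13 and 28 in order of time. At 0 days 48 were higher and 22 lower in the wild type, or 28 and 25 after quantile normalization, and at 0.5 days 33 and 10, or 21 and 13. At 6 days 19 were higher and 9 lower, but 3 and 38 after quantile normalization. At 2 days 2 were higher and 3 lower, and 8 and 0 after quantile normalization. At 4 days all 13 were lower.

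The median difference of the immunity genes was -0.11 in untreated plants and -0.06, 0.05, -0.22 and -0.27 at 0.5, 2, 4 and 6 days. It lay at percentiles of 0, 0.01, 0 and 0 among matched random lists at 0, 0.5, 4 and 6 days. At 2 days it lay at percentile 96.5. List members can vary together, which the probes of random lists need not, so percentiles here and below overstate the evidence. The salicylic acid list stood at -0.06, -0.07, 0.09, -0.29 and -0.29 in order of time, at percentiles of 8.84, 5.0, 94.3, 0.05 and 0.075, and its 3 members were higher in the wild type at 2 days. The jasmonate and ethylene list stood at -0.56 at 0.5 days and -1.31 at 4 days, both at percentile 0. It stood at -0.00088 at 0 days (percentile 33.6) and 0.11 at 2 days (percentile 98.4). At 6 days it was -0.04 (percentile 15.8), and 0.0052 after quantile normalization. The list held only PDF1.2, PDF1.2b and THI2.1, and its highest member was at -0.0087 at 0.5 days and -0.027 at 4 days. The added list of 11 jasmonate and defensin genes stood at -0.02 at 0.5 days (percentile 20.1) and -0.10 at 4 days (percentile 0.04). The cold list stood at 0.13, 0.25, 0.10, 0.40 and 0.41 in order of time. Nuclear photosynthesis genes stood at 0.07, 0.44, -0.30, 0.20 and 0.58 in order of time, at percentiles of 24.7, 100, 22.6, 99.99 and 100. After quantile normalization they stood at -0.10, 0.26, 0.0033, 0.13 and 0.34, with the sign changed at 0 and 2 days. The wild type column of 2 days and the rpp4 column of 6 days were the narrow ones.

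**Figure D2:**
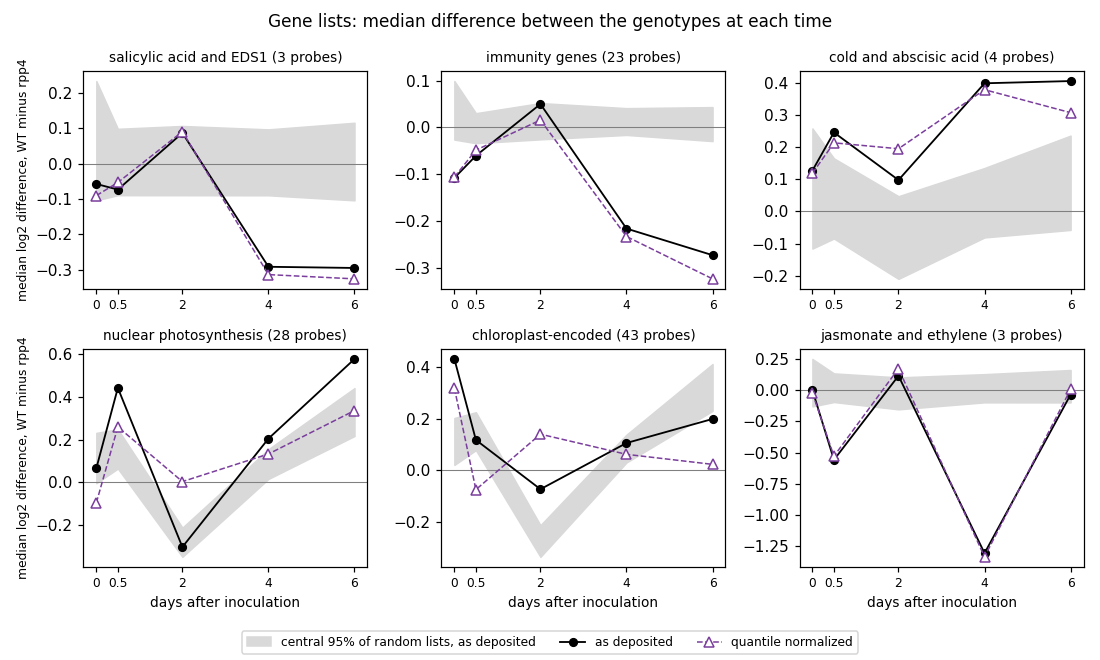
Median log2 difference of wild type minus rpp4 for 6 gene lists against days after inoculation, as deposited (black circles) and after quantile normalization (open triangles), with the central 95% of matched random lists in grey. The immunity genes stood at -0.27 at 6 days and the cold and abscisic acid genes at 0.41.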

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

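The tests of other splits, of the narrow columns and of a larger late response in this part were chosen after the result was seen.

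The count of 73 probes whose genotype difference moved along the time course stood out because the trend tests the difference between the genotypes at early and late times. Of the 75 drawn splits of the 10 columns for which the trend could be fitted, the real one included, 15 gave as many calls. At each time that a split parts, it keeps or reverses the real genotype difference, so the splits are not free of genotype. Their counts cannot show whether the real calls arose by chance, and chance was not excluded. The highest other split gave 1381, many times the real count, which points to a structure of the samples. It parts the columns of 3 times only, and after quantile normalization it still gave 899 calls. For the genotype over all times, with 21 calls, 10 of 100 splits gave as many and the highest other gave 2188. These splits also keep or reverse the real differences, so the count cannot decide, and chance was not excluded there either. Splits that leave a time unparted can give the same fit, and with each fit counted once 11 of 48 gave as many for the trend and 6 of 53 for the genotype. The 16 splits that part the columns of every time, as the real one does, are too few for a share under 0.05. Of these 16, the real one included, 4 gave as many calls for the trend and 2 for the genotype. Among them, for the trend, an exchange of 4 and 6 days gave 1236 calls, one of 2, 4 and 6 days 915 and one of 0.5, 2, 4 and 6 days 152, which after quantile normalization fell to 17, 34 and none, as the real split fell to none. For the genotype the split of 2188 calls exchanges the columns at 2 days only, another structure of the samples, and after quantile normalization neither it nor the real split gave any call.

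Probes that rose by at least 1 at 4 days in both genotypes stood higher in rpp4 at 6 days, with a median difference of -0.53 after quantile normalization, at percentile 0 of matched random lists, with 23 of 25 higher in rpp4, and already at 0.5 days (-0.27, percentile 0, 24 of 25). With equal ranges the median at 6 days lay outside the central 95% of random lists. As deposited it was -0.36 for 23 probes, while the central 95% of matched random lists ran from 0.097 to 0.30. Probes of this brightness thus leaned towards the wild type beside the narrow rpp4 column, against the pattern. These deposited values argue against the narrow range as the cause. The outcome with equal ranges could be foreseen from them and adds no support. For a larger late response of the susceptible mutant, the criterion also asked the probes that fell to lie above the central 95%, and it was missed after quantile normalization (median 0.28, 6 probes, percentile 97.46) but met as deposited (0.40, 10 probes, percentile 98.84). Larger sets chosen at 6 days and read at 4 days after quantile normalization ran the same way, 41 probes that rose at -0.40 (percentile 0) and 36 that fell at 0.20 (percentile 100), though the criterion was not set on them. The missed value would count against this explanation but for a margin for random-draw error, set after the value was seen. That margin was a multiple of the standard error of the random draw, 0.157. At 0.5 days the sets chosen at 6 days already stood apart in the same directions after quantile normalization, at -0.37 (percentile 0) and 0.29 (percentile 100). The 6 probes that fell at 4 days stood at 0.27 at 0.5 days (percentile 99.8). The pattern was thus not confined to late times and does not show that the response was larger late. A larger late response may be present but stays open. The medians are levels at 1 time and not changes from 0 days, so a difference present before inoculation would count too. The immunity genes already stood at -0.11 at 0 days (percentile 0), and at -0.27 at 6 days. Each group also had 1 column, and inoculation, age and time of day were not separated.

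The same probes that rose at 4 days stood higher in the wild type at 2 days, by a median of 0.21 after quantile normalization, at percentile 100, with 4 of 25 higher in rpp4. With equal ranges this median lay outside the central 95% of random lists. As deposited it was 0.061 for 23 probes, while the central 95% of matched random lists ran from -0.27 to -0.13. Probes of this brightness thus leaned towards rpp4 beside the narrow wild type column, against the pattern. For these probes the deposited values argue against the narrow range as the cause, and the outcome with equal ranges adds no support. The 41 probes that rose at 6 days had a median of 0.059 at 2 days after quantile normalization (percentile 96.8), within the central 95%, and as deposited 25 of 37 were higher in rpp4 (-0.15, percentile 98.1). The 36 that fell at 6 days had a median of -0.12 (percentile 0, 29 higher in rpp4), and as deposited 59 had -0.33 (percentile 0.02). The 6 that fell at 4 days had -0.063 at 2 days after quantile normalization (percentile 14.4), within the central 95%. As deposited 10 had -0.34 (percentile 2.15), so the narrow range stays open for the probes that fell at 4 days. An earlier response in resistant plants was not tested, and exchanged labels at 2 days stay open.

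The control probe for 5S ribosomal RNA was fitted with all probes but is not one of the genes the comparisons are about, and it rose by 1.44 at 0.5 days on the log2 scale (adjusted p = 2.05e-07, limma).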

How the results depend on the processing

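The alternatives without a pseudocount and without the narrow columns, and those of the added lists, were chosen after seeing the data. Without the narrow columns, 2 days rests on rpp4 alone and 6 days on the wild type alone. No paired analysis was possible because, for pairing by replicate number, each group would need a column per replicate, and replicates 1 and 2 share 1; the genotypes were compared within each time. Of the named genes in the alternatives run for them, none that was called changed direction. Counts of calls moved as follows, and the cause was not tested except where fewer columns or a further threshold were used by construction. Dim probes and the scale of the deposited values limit what small changes can show.

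After quantile normalization the genotype gave 0 calls, 2 days against 0 days 12 and the genotype by time trend 0, and 8 probes were at least 1 apart between the genotypes at 2 days. Of 115 list medians of the difference at single times, 26 changed sign, and 13 with centred columns. Those outside the central 95% of random lists as deposited were the chloroplast-encoded genes at 2 days (0.14), autophagy at 6 days (-0.15, and -0.0065 with centred columns) and BGLU at 0.5 days (0.0087). With columns centred on their medians the genotype by time trend gave 15. Without the dimmest 40% of probes the genotype gave 0, 2 days against 0 days 4 and the genotype by time trend 0. With eBayes without trend the genotype gave 0, 2 days against 0 days 0 (2108 at unadjusted p under 0.05), 4 days against 0 days 408, 6 days against 0 days 1167 (869 higher and 298 lower) and the genotype by time trend 0. With a pseudocount of 32 these were 0, 1, 336, 1516 and 0. With no block the genotype gave 0, and 2, 4 and 6 days gave 3, 390 and 1431. With a log2 difference of at least 1 asked for, the genotype gave 0, 0.5 days against 0 days 158, and the later times 18, 118 and 243. At unadjusted p under 0.05 the genotype had 1264 probes without dim probes, 1314 without trend, 1297 with a pseudocount of 32 and 231 with no block, and the genotype by time trend 1011, 1024 and 1279 (limma).

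Without a pseudocount the genotype gave 34, 2 days against 0 days 145 (93 higher and 52 lower) and the genotype by time trend 10 (3 towards the wild type and 7 towards rpp4). Without the narrow columns the genotype gave 0 (3624 at unadjusted p under 0.05), 2 days against 0 days 0, 6 days against 0 days 667 and the genotype by time trend 15. Leaving out 1 time gave 0 to 34 calls for the genotype, 171 to 302 for 2 days against 0 days and 127 to 201 for the genotype by time trend. With an estimated correlation, and with fry, 0 of the fixed and 0 of the added lists were called for the genotype or for the times, with smallest adjusted p of 0.107 and 0.143 for gene lists genotype, 0.264 and 0.076 for gene lists time, 0.485 and 0.41 for added gene lists genotype and 0.694 and 0.103 for added gene lists time.

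Of 175 values of named genes, called or not, 56 lost their call after quantile normalization, 104 with eBayes without trend, 87 with a pseudocount of 32, 83 without the narrow columns and 13 with centred columns. Uncalled genotype differences near 0 changed sign for THI2.1 (-0.018 to 0.042 leaving out 1 time, -0.012 without the narrow columns), LTI30 (-0.0061 without the narrow columns), COR47 (0.0013 with a pseudocount of 32, -0.080 to 0.063 leaving out 1 time), MUTE (-0.0088 to 0.044 leaving out 1 time, -0.0015 without the narrow columns) and FMA (-0.0012 after quantile normalization, -0.00063 with centred columns, -0.039 to 0.041 leaving out 1 time).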

Other observations

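The test of the narrow column at 2 days and the count over all gene records around RPP4 were chosen after the result was seen.

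Single members of other gene families were called over both genotypes. UGT72E1, a glycosyltransferase gene of lignin precursors, rose by 0.77, 0.73 and 1.18 at 2, 4 and 6 days on the log2 scale, and the defensin gene PDF1.4 rose by 1.13 ± 0.15 at 6 days. THI2.2, a thionin gene, fell by 1.31 at 0.5 days, and BGLU40 fell by 0.74, 0.63 and 0.91 at 0.5, 4 and 6 days. Without the narrow columns UGT72E1 at 2 days (adjusted p = 0.602, limma) and THI2.2 (0.0557) were not called. The UGT, jasmonate and defensin, and BGLU lists did not rank apart at those times, except for UGT at 4 days after quantile normalization (camera adjusted p = 0.0472).

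The genotype difference at 2 days ran against that at the other times, with a correlation of -0.44 across probes, which are not independent replicates, with the mean of the other differences. After quantile normalization the correlation was -0.11, which is consistent with the narrow range of the wild type column at 2 days as a source of much of it. Exchanged labels at 2 days could give the same picture, and of 25 probes with 1 sign and at least 0.4 apart at the other times after quantile normalization, 13 or 52% kept that sign at 2 days, between the at most 20% that an exchange and the at least 60% that correct labels were set to give. As deposited, 9 of 22 kept it, and with lower thresholds of 0.3 and 0.2 the shares were 44.8% and 40.5% after quantile normalization and 24.4% and 14.8% as deposited. The labels at 2 days stay open, because the value set to decide lay between both bounds.

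Of the 15 genotype calls with 1 gene, 1 lay within 200 genes of RPP4, the pseudogene AT4G16870, which was higher in the wild type by 0.36 ± 0.05. That is 6.67% of calls against 1.28% of probes, a ratio of 5.21 (Fisher's exact test, two-sided, p = 0.176), and 0 of 14 over protein-coding genes alone (p = 1), where the count over all records was chosen after this was seen. The locus code of this pseudogene lies close to that of RPP4, AT4G16860. A count within 200 genes takes no account of that nearness, and no test of it was run. A segment around RPP4 that differs between the lines may add to the calls, but with 1 call near RPP4 the count cannot decide.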
